A study of Homo sapiens with 5 samples.

How the data were processed

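The 5 libraries were made from polyA RNA of DLD-1 cells, isolated with a column kit and DNase treatment and prepared by standard Illumina protocols, per the labels. The groups are a control, WBP11 siRNA and SNW1 siRNA (each 100 nM, 72 h), and a control and a WBP11 degron line under 500 µM auxin for 48 h, with 1 library each. The labels do not say whether the control received a non-targeting siRNA.

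The deposited files are 3 tables, each of 1 depleted library against 1 control. Per the file headers, they are comparisons by IRFinder of STAR genome alignments to hg38, and the submitters' processing notes name RSEM, bedtools and hg38. Versions are not given in the sources used here. The intron retention ratio is a fraction per the file headers: the intron's depth over that depth plus the spliced reads. The intron depth is a coverage signal as deposited, over the bases of the intron that IRFinder measures, and the spliced reads are deposited as a count per intron. None of these was scaled between libraries. The ratio compares an intron with the splicing at its own ends, so library size cancels, but reads of overlapping exons or genes can count as retention. The name field marks introns that overlap an annotated exon, 5.26%, 4.12% and 4.05% of those listed. The deposited p-values compare the reads of 2 libraries and are unadjusted, and a code of 33 stands where no test was made. IRFinder's warnings, such as uneven coverage, were kept as information. Every listed intron had no warning in at least 1 of the libraries and reached 1% in at least 1. All 34560 introns matched introns of GENCODE release 29 exactly, which gave intron numbers and coding or UTR position. Coordinates are hg38, counted from 1. Gene names are current symbols found through the gene identifiers, and 9, 19 and 24 rows had identifiers without a match.

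The control library of the RNAi tables had the same depths and spliced reads in both. It was therefore treated as shared.

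An intron was tested when its depth plus spliced reads was at least 10 in both libraries. This left out 561, 711 and 643 introns. Higher and lower mean a difference in retention of at least 0.1, which the design fixed for fractions. The design set no depth minimum for fractions, and the 10 was chosen before any result was computed. Retention ratios have Wilson 95% intervals and differences Newcombe 95% intervals, with depth plus spliced reads as the number of observations. Reads are not independent molecules and depth is an average over bases, so the intervals cover counting error only. No model was fitted and no p-value was computed from the libraries, because each group had 1. Unchanged libraries were simulated 100 times by drawing both libraries from the pooled ratio at the observed depths. Where an intron rose, its pooled ratio lies above that of the control, which adds simulated falls. A number of falls at or under the simulated one therefore cannot be read as noise alone. Spliced reads of WBP11 and SNW1 were set relative to the total of listed introns, which is part of the library and not its depth.

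Gene lists, 13 in all, were fixed before the data were examined. The median change of a list's introns was placed among 10000 random lists of as many introns, drawn within 10 classes of mean retention. Mean retention averages the depleted and control libraries, so this matching is not independent of the change and can absorb part of a rise. Changes were taken as differences in place of log2 ratios, since the unit was a fraction. Overlaps were set against the product of the list sizes over the introns tested in both. For the shared control, unchanged libraries were simulated against 1 common draw.

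Named genes follow a rule fixed before the data were examined: WBP11 and SNW1, TUBGCP6 and CDCA5, the 10 genes with the largest rise and the 5 with the largest fall, up to 2 rises and 1 fall per gene list, and the 5 introns higher in all comparisons with the largest smallest rise. Other members of lists are named only where a count is spelled out. Some genes that the rule names are not reported here. The rule as fixed ranked by log2 ratio; because the unit was a fraction, genes were ranked by the difference in retention instead, which departs from it. No adjusted p was part of the table, so none was used to choose genes.

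The calls were tested on simulated data with 200 planted changes per comparison. Changes of 15 points were recovered in 87%, 90% and 91% of introns, and changes of 30 points in 99%, 99% and 100%, over 16068, 23366 and 21828 introns of WBP11 RNAi, SNW1 RNAi and WBP11 auxin. Alternatives were other size rules, no and stricter depth minimums, other pseudocounts, median centring, 1 intron per gene for the counts, and unmatched lists. Added after seeing the data were other differences, a 2-fold rule with a pseudocount of 0.01, adjusted deposited p-values, warnings and known exons for the counts. Added for the lists were random lists matched on depth, 1 intron per gene, and log2 ratios with a pseudocount of 0.01, the setting nearest to the statistic the design fixed. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. GC content and splice site strength were not analysed here.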

Results

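Intron retention was measured in 5 polyA RNA sequencing libraries of DLD-1 cells, a human colorectal adenocarcinoma line, with 1 library in each group. WBP11, a splicing factor that joins the spliceosome and binds protein phosphatase 1, was lowered with 100 nM siRNA for 72 h. SNW1, a component of the activated spliceosome also known as SKIP, was lowered in the same way. Both were set against 1 control library, which the labels give no treatment and the file headers call control RNAi. In a separate pair of libraries, cells that carried only a degron-tagged WBP11 transgene in place of the endogenous gene received 500 µM auxin for 48 h, which marks the tagged protein for degradation, and control cells with the plant auxin receptor received the same auxin. The question was which introns stay in polyadenylated RNA when either factor is missing.

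Each value is an intron retention ratio, the share of transcripts at an intron that kept it, as deposited. The tables listed 16629 introns for WBP11 RNAi, 24077 for SNW1 RNAi and 22471 for WBP11 auxin. The listed introns held 2987572 spliced reads in the WBP11 RNAi library against 3146434 in its control, 4170988 after SNW1 RNAi against 5527186, and 4927556 after WBP11 auxin against 4276828 in the auxin control. The median depth behind a retention ratio lay between 98.8 and 125 over the 6 columns of the tables. With 1 library per group, no difference has a replicate check, and every interval covers counting error within these libraries only. An intron was called higher or lower when its ratio differed by at least 10 percentage points. "Rose" and "fell" are used in this sense.

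The targeted genes came first. WBP11 (ENSG00000084463.6, chromosome 12, minus strand) kept 6.75% of its spliced reads in the WBP11 RNAi library (95% interval 4.07 to 10.6, 20 reads against 312 over its 2 listed introns), relative to the total of listed introns. SNW1 (ENSG00000100603.12, chromosome 14, minus strand) kept 10.2% in the SNW1 RNAi library (6.87 to 14.8, 31 reads against 401 over 2 introns). WBP11 itself stood at 196% of control after SNW1 RNAi (181 to 212, over 5 introns). SNW1 stood at 141% after WBP11 RNAi (125 to 160), from 1 listed intron only, its last, with 627 reads against 467. In the auxin pair, where the protein and not the mRNA is the target, the only listed WBP11 intron lies in the 5' UTR and had 103 spliced reads against 235, which is 38.0% (29.9 to 48.2). That intron cannot show whether the tagged protein was lost. SNW1 stood at 65.3% in the same pair (56.5 to 75.5), judged from its last intron, which itself rose as described under WBP11 auxin. Adding 10 reads to each mean moved the WBP11 RNAi value to 12.7% and the SNW1 RNAi value to 16.1%.

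WBP11 RNAi raised the retention of 1457 introns in 886 genes and lowered that of 272, out of 16068 introns in 5725 genes that passed the depth minimum. The largest rises were in CLTCL1, a clathrin heavy chain, from 8.0% to 78.4%, and in ZFYVE19, from 12.0% to 81.5%. RNF123, a ubiquitin ligase subunit, went from 4.35% to 70.6% (difference 66.2 points, 95% interval 52.6 to 75.8) at a 71 bp intron on chromosome 3 between 49700565 and 49700635, intron 14 of 38 and within the coding region. NRBP2, ATP13A1, PEAR1, ZNF276, PARP10, PLCD1 and RHPN1 were the others, with differences between 57.4 and 67.7 points. Of these 10 introns, that of CLTCL1 rested on a depth of 18.5, that of NRBP2 on 15.2, that of PEAR1 on 12.3 and that of RHPN1 on 16.9 in the depleted library.

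Falls after WBP11 RNAi were ranked by the difference, so the largest could only be at introns that the control kept often. OGT, which encodes the O-GlcNAc transferase, fell from 81.3% to 37.5% (difference -43.8 points, -52.2 to -34.3) at its intron 4 of 21, X chromosome 71544636 to 71547906. EPOR, the erythropoietin receptor, fell from 59.6% to 11.7% and IL17RB from 46.1% to 5.12%, and MAMDC4 and SMPD4BP completed the 5. Unchanged libraries simulated with counting noise alone gave 273 lower and 296 higher introns on average. The number of rises was far above the simulated one and the number of falls was close to it. Introns that rose add simulated falls through the pooled ratio, so the falls cannot be read as noise from this. The interval of the difference lay above 0 for 1138 of the 1457 rises and below 0 for 128 of the 272 falls.

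TUBGCP6 (ENSG00000128159.10), a γ-tubulin complex protein needed for centriole duplication and fixed as a gene of interest before the data were examined, had 4 of 16 listed introns higher after WBP11 RNAi. The strongest were intron 18 of 24 (chromosome 22, 50219457 to 50219643), from 39.5% to 75.5%, and intron 20 (50218898 to 50219067), from 6.40% to 40.2% (difference 33.8 points, 20.9 to 46.1). Introns 17 and 6 rose from 0.781% to 18.5% and from 4.18% to 21.1%. The other 12 listed introns stayed within 10 points. CDCA5 (ENSG00000146670.8), which encodes the cohesion factor sororin, rose at intron 1 of 5 (chromosome 11, 65083724 to 65083932) from 3.77% to 29.9% (difference 26.1 points, 16.6 to 33.4), and its other 4 listed introns stayed within 10 points.

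Among the gene lists, sister chromatid cohesion had 8 of 54 introns higher in 4 genes, CDCA5, CHTF18, DDX11 and ESPL1, and none lower. Its median change of 1.62 points was at percentile 99.7 of random intron lists matched on mean retention. DNA replication genes had 7 of 80 introns higher, led by POLD1, a DNA polymerase δ subunit (5.32% to 28.5%), and RFC4, a clamp loader subunit (20.9% to 44.1%), and were at percentile 99.3. In the γ-tubulin list 6 of 40 introns rose, in TUBGCP6 and TUBG2 (29.1% to 51.9%), at percentile 94.4. In 7 other settings the γ-tubulin list lay between percentiles 72.7 and 99.25. Of these settings, 3 newly put it in the outer tail of the random lists. Centriole and centrosome genes had 10 of 110 higher, with CEP350 (63.9% to 97.7%) and TEDC2 (49.3% to 82.0%) in front, and 2 lower, in CNTROB (40.6% to 29.1%, interval of the difference -25.2 to 2.73) and at 1 intron of WDR62 (13.0% to 1.48%, -27.9 to 0.968), at percentile 77.0. The CEP350 intron overlaps an annotated exon and had 1 spliced read against 10, with a warning of low splicing. Homologous recombination and Fanconi genes had 13 of 98 higher, among them the helicase RECQL4 (25.9% to 75.1%) and ATM (0% to 47.9% at a depth of 13.4), at percentile 86.8.

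SR protein and snRNP genes were on the other side after WBP11 RNAi. None of the 38 measured introns of SR proteins and CLK kinases rose and 2 fell, in SRSF1 and SRSF2 (19.9% to 8.44% at the 3' UTR intron of SRSF2), and the list was at percentile 0.18. Both introns that fell overlap an annotated exon. U1 and U2 snRNP genes had no intron higher among 37 and U2AF2 lower (14.0% to 3.76%), at percentile 1.44. The list of PRPF19 complex, activated spliceosome and related factors had 0 of 60 introns higher or lower, at percentile 5.48. Anaphase-promoting complex and spindle checkpoint genes had 2 introns higher, in CDC27 and ANAPC7, and 3 lower, in ANAPC2 (24.5% to 7.35%), ANAPC4 and BUB1B, at percentile 2.23. Proteasome genes had 1 of 38 higher (PSMB4, 3.50% to 19.1%), ribosomal protein genes 0 of 8, and p53 targets 3 of 30, led by PLK3 (1.77% to 13.6%) and TNFRSF10B (56.6% to 67.7%); these lists were at percentiles 28.9, 50.1 and 53.1. Of the fibroblast and leukocyte markers, 1 intron was measured. The places of the cohesion, replication and anaphase-promoting complex lists beyond the outer 2.5% were lost in 4, 4 and 5 of 7 other settings (4 planned, 3 added after seeing the data), in which their percentiles reached 87.95, 89.1 and 23.8. Introns of a gene are not independent, and the percentiles describe these libraries only.

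SNW1 RNAi raised 3876 introns in 1908 genes and lowered 84, out of 23366 introns in 6965 genes. Retention was above control at 91.3% of the introns, with a median change of 2.63 points, against 59.6% and 0.756 points after WBP11 RNAi. PRKDC, the catalytic subunit of DNA-dependent protein kinase, went from 0.120% to 73.1% (difference 72.9 points, 67.8 to 77.4) at the 67 bp intron 82 of 85, chromosome 8, 47778661 to 47778727, on depths of 334 and 322. CDCA5 was among the 10 largest rises, at the same intron 1, from 3.77% to 69.2% (difference 65.4 points, 54.0 to 73.5). HINT2, a mitochondrial hydrolase, went from 7.83% to 77.2%, EPHX2, the soluble epoxide hydrolase, from 7.79% to 74.9%, and LMF2 from 21.4% to 88.0%. DNHD1, MFSD13A, DNAAF3, RHBDL1 and WDR90 made up the rest, with depths of 14.8 to 34.0 in the depleted library.

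The 84 falls after SNW1 RNAi were fewer than the 400 that counting noise gave on average in unchanged libraries, whereas the noise gave 425 rises against the 3876 observed. OGT intron 4 fell here too, from 81.3% to 52.4% (difference -28.9 points, -37.9 to -19.6), and LAMB2, a laminin subunit, fell at its first intron, which overlaps an annotated exon, from 99.7% to 70.2%. NEK1, AHNAK2 and FASTKD1 were the other 3 of the 5 largest, the last with an interval that reached 0.563 points. In the SNW1 table the interval of the difference lay above 0 for 3216 of the rises and below 0 for 33 of the falls.

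TUBGCP6 had 12 of 17 listed introns higher after SNW1 RNAi and none lower. Intron 20 went from 6.40% to 38.9%, intron 6 from 4.18% to 34.4%, intron 23 from 36.1% to 62.8%, and intron 4 from 0.457% to 20.4%. Introns 24, 21, 11, 10 and 9 stayed within 10 points. In the γ-tubulin list 18 of 48 introns rose, in TUBG1, TUBG2 (29.1% to 68.1%), TUBGCP4 and TUBGCP6. The list was at percentile 72.8, with a median gain of 4.70 points against 4.22 in random introns of like mean retention. That mean includes the depleted library, so the match can absorb part of a rise. The share of introns higher was 37.5% in this list and 16.6% over all introns tested. In 7 other settings it lay between percentiles 27.7 and 99.66. Of these settings, 2 newly put it in the outer tail of the random lists.

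**Figure D1:**
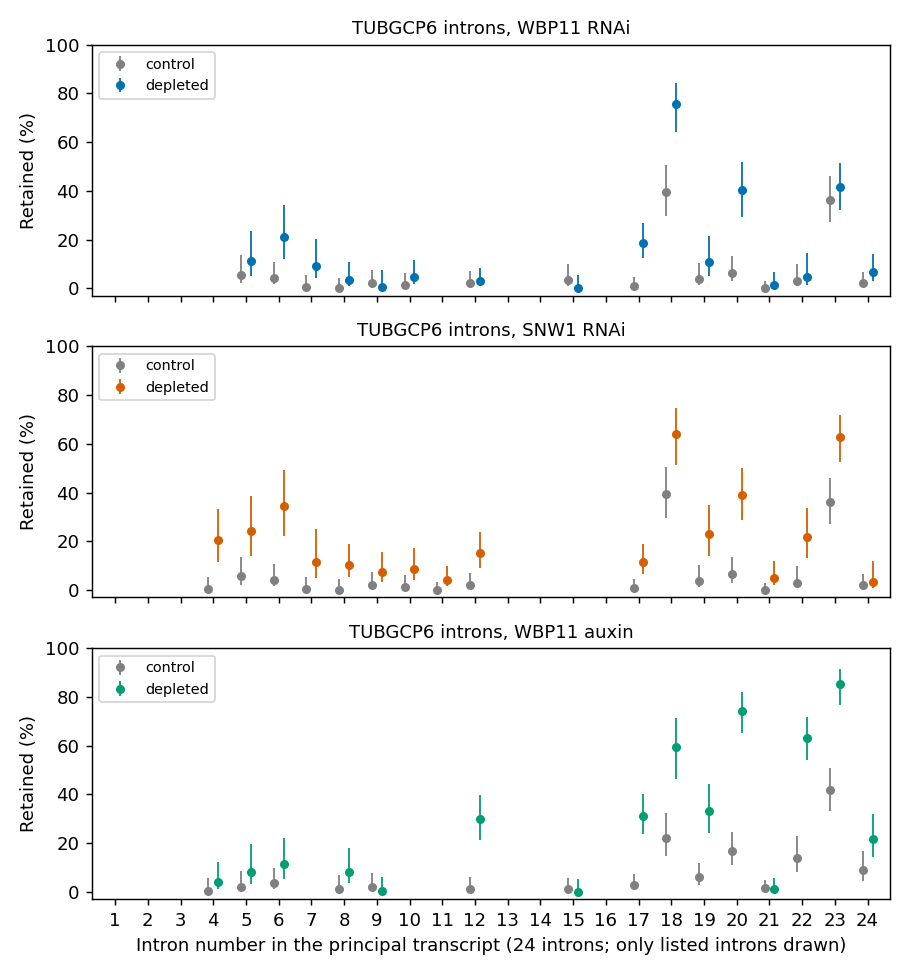
Retention of each listed TUBGCP6 intron (y axis, percent) by its number in the principal transcript (x axis), in control (grey) and depleted (coloured) libraries, with Wilson 95% intervals for counting error and 1 library per point. Introns 17, 18 and 20 are higher in all 3 comparisons, and 4 of 16, 12 of 17 and 8 of 15 listed introns are higher after WBP11 RNAi, SNW1 RNAi and WBP11 auxin.

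Other lists differed in their share of introns higher after SNW1 RNAi. It was 28.8% for recombination and Fanconi genes and 9.35% for replication genes, against 16.6% of all introns tested. The list percentiles depended on the setting. In 7 other settings they ran from 13.4 to 99.93 for recombination and Fanconi genes. The ranges were 24.5 to 99.25 for cohesion genes and 0.8 to 21.0 for replication genes. Homologous recombination and Fanconi genes had 32 of 111 introns higher in 12 genes, led by RECQL4 (27.0% to 75.5%) and RECQL5 (46.8% to 81.3%), at percentile 71.2. Cohesion genes had 14 of 59 higher, with CDCA5 and the separase gene ESPL1 (9.68% to 61.2%, depth 11.9), at percentile 67.8. Anaphase-promoting complex genes had 11 of 76 higher, led by ANAPC2 (11.5% to 67.2%) and CDC16 (73.5% to 94.4%), at percentile 13.3, replication genes 10 of 107, led by POLD1 (5.32% to 32.1%) and ORC2 (14.3% to 37.8%), at percentile 7.66, and p53 targets 9 of 46, led by TNFRSF10B (56.6% to 80.8%) and PLK3 (9.18% to 32.8%), at percentile 77.8. Centriole and centrosome genes had 24 of 144 higher, among them CEP131 (4.88% to 56.5%) and CEP350 (63.9% to 94.6%), at percentile 3.33.

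U1 and U2 snRNP genes had 1 of 59 introns higher, in SF3B2 (2.06% to 15.1%), and were at percentile 0.70. SR proteins and CLK kinases had 1 of 58 higher, in SRSF6 (13.3% to 38.4%), and were at percentile 0.93, which became 18.6 with lists matched on depth, 3.62 with 1 intron per gene and 3.04 with unmatched random lists. The list of PRPF19 complex, activated spliceosome and related factors had 1 of 119 introns higher, in SNW1 itself (0.228% to 13.9%, depth 16.3). The list was at percentile 42.8. Ribosomal protein genes had 1 of 22 higher, in RPL10 (2.19% to 20.4%), at percentile 42.6. Proteasome genes had 1 of 69, in PSMB4 (3.50% to 14.9%), at percentile 20.5. No intron of the fibroblast and leukocyte markers was measured.

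In the WBP11 auxin pair 3015 introns in 1752 genes rose and 298 fell, out of 21828 introns in 6789 genes. The depleted library came from the degron line and its control from other cells, both with auxin. The series holds no library of the degron line without auxin. Differences between the lines therefore cannot be told apart from loss of WBP11. The largest rises named here were all at introns of 69 to 86 bp. OSBP, the oxysterol-binding protein, went from 1.22% to 83.5% (82.2 points, 78.6 to 85.1) at the 85 bp last intron, chromosome 11, 59576720 to 59576804. KDM6A, a histone demethylase, went from 0.856% to 82.2%, CNOT11, a CCR4-NOT subunit, from 10.5% to 90.9%, and PGAP6 from 5.06% to 82.5%. GOLGA7B, PC, VLDLR, MAP3K6 and COG6 were also among the largest rises, and of these VLDLR had a control depth of 11.0 and GOLGA7B depths of 19.4 and 16.0.

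Of the target genes, SNW1 rose at its last intron after WBP11 auxin (chromosome 14, 77718287 to 77718366, 80 bp, overlapping an annotated exon), from 4.75% to 57.5% (difference 52.7 points, 48.5 to 56.5). The same intron stood at 7.58% against 3.20% after WBP11 RNAi, a difference of 4.38 points (1.73 to 6.94). The largest falls after auxin were in SETD4, ZDHHC8, USP39, PRPF4B and KRT15. USP39, a splicing factor, fell from 73.8% to 37.0% (difference -36.8 points, -44.6 to -28.1) and PRPF4B, a kinase that acts on the spliceosome, from 78.1% to 41.6%, each at an intron of the 3' UTR that overlaps an annotated exon. Counting noise alone gave 439 rises and 464 falls on average, so the number of falls, 298, did not exceed the simulated one. The interval of the difference lay above 0 for 2479 of the 3015 rises and below 0 for 152 of the 298 falls.

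TUBGCP6 had 8 of 15 listed introns higher after WBP11 auxin and none lower. Intron 20 went from 16.8% to 74.4% (difference 57.6 points, 45.4 to 67.0), intron 22 from 14.1% to 63.3%, intron 23 from 41.7% to 85.6% and intron 12 from 1.12% to 29.9%, and introns 17, 18, 19 and 24 were the other 4. CDCA5 rose at 3 of its 4 listed introns. Intron 3 (65083400 to 65083484, 85 bp) went from 0.869% to 39.9%, intron 2 from 3.01% to 26.6% and intron 1 from 21.2% to 33%.

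The gene lists after WBP11 auxin had rises in nearly every group. Anaphase-promoting complex and spindle checkpoint genes had 15 of 67 introns higher in 10 genes, led by ANAPC5 (8.95% to 62.9%) and ANAPC2 (10.9% to 62.2%), at percentile 98.96. The ANAPC2 values here and after SNW1 RNAi are of the intron at 137180385 to 137180451 on chromosome 9. The ANAPC2 fall after WBP11 RNAi was at another intron, 137185088 to 137186223. Cohesion genes had 16 of 83 higher and 1 lower, led by the centromere protector SGO1 (0.821% to 44.3%), at percentile 98.5, with CHTF18 the lower one (50.3% to 31.7%). Replication genes had 20 of 131 higher, led by POLE (21.8% to 86.2%) and RFC4 (34.8% to 86.5%), at percentile 87.8, and recombination and Fanconi genes 24 of 145, led by RECQL4 (27.0% to 80.9%) and FANCI (21.7% to 74.9%), at percentile 90.8. Centriole and centrosome genes had 24 of 169 higher, led by CEP131 (16.7% to 77.2%) and HAUS5 (13.7% to 63.3%), with OFD1 lower at another intron (12.3% to 0.773%), at percentile 48.2. In the γ-tubulin list 9 of 49 introns rose, in TUBGCP6 and CDK5RAP2 (4.74% to 16.8%), and 1 fell, at percentile 11.6. That fall was in TUBG2 (20.6% to 9.0%), at another intron than the TUBG2 values given for the RNAi comparisons. The cohesion list lost its place in 3 of 7 other settings, down to percentile 84.9, and the anaphase-promoting complex list in 1, with unmatched random lists, at 94.6.

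In the SR protein and CLK kinase list 6 of 40 introns rose, led by CLK4 (0% to 36.3%) and CLK1 (10.5% to 35.8%) after WBP11 auxin, and the list was at percentile 0.73, which became 10.7 with 1 intron per gene. U1 and U2 snRNP genes had 6 of 39 higher, among them SF3B2 (0.221% to 39.7%), at percentile 11.3. The list of PRPF19 complex, activated spliceosome and related factors had 6 of 76 higher, led by SNW1 and RBM22 (3.76% to 32.3%). In this list DHX38 was lower (23.7% to 13.1%), and the list was at percentile 8.52. Proteasome genes had 8 of 59 higher, led by PSMC5 (2.24% to 22.9%) and PSMB4 (3.54% to 16.7%), at percentile 36.7, and ribosomal protein genes 1 of 22, in RPL10 (6.90% to 21.7%), at percentile 3.67. The p53 targets had 4 of 47 introns higher, led by FDXR (15.2% to 32.4%) and DDB2 (17.1% to 32.2%, interval of the difference -0.813 to 32.1), and their median change of 0.107 points was at percentile 0.03. No fibroblast or leukocyte marker intron was measured.

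**Figure D2:**
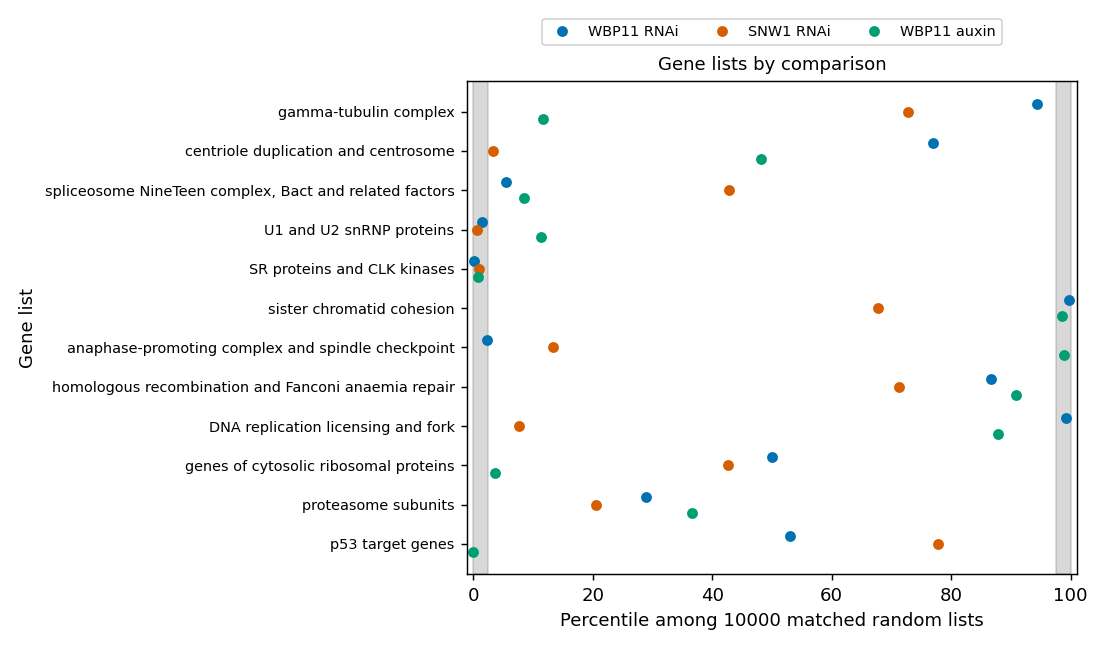
Place of each gene list's median retention change among 10000 random intron lists matched on mean retention (x axis, percentile), for the 12 lists with enough introns (y axis), by comparison (colour); grey bands mark the outer 2.5% at each end. SR proteins and CLK kinases are in the lower band at 0.18, 0.93 and 0.73. The SNW1 RNAi value leaves it in 3 of 7 other settings, farthest with lists matched on depth (18.6), and the auxin value in 1, with 1 intron per gene (10.7).

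Over the 3 comparisons 36 list percentiles were computed and 11 lay in the outer 5%, where 1.8 would if all introns were independent. Introns of a gene are not, some lists share genes, and the RNAi comparisons share a control, so the 11 cannot be judged against 1.8. Only the p53 list after auxin, the U1 and U2 list after both RNAi treatments and the SR and CLK list after WBP11 RNAi kept their place in all 7 other settings.

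The WBP11 RNAi and WBP11 auxin comparisons, with separate control libraries, had many higher introns in common. Of 10391 introns tested in both, 723 were higher in both, against 223 for independent lists, which is 66.8% of the RNAi rises and 33.7% of the auxin rises. Lower in both were 39 against 2.73, while counting noise in unchanged libraries gave at most 27. Across introns, which are not independent replicates, the changes had a Pearson correlation of 0.511 and a Spearman correlation of 0.472.

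The 2 RNAi comparisons shared their control. Of 12751 introns tested in both, 947 rose in both, against 286 for independent lists and at most 74 in unchanged libraries compared with the same control. The covariance of the changes was 43.0 squared points against 5.82 simulated. The control cannot be split, so part of the excess may come from it. The 45 introns lower in both were fewer than the 85.0 that unchanged libraries with 1 control gave on average. SNW1 RNAi and WBP11 auxin, with no library in common, shared 1154 rises of 13028 introns against 470 for independent lists.

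In all 3 comparisons 501 introns of 353 genes were higher, out of 8601 tested in each, where independent lists give 53.9 and unchanged libraries, with the RNAi control shared, at most 9. Part of the excess may come from the shared control. Taken once per gene, the strongest by their smallest rise were in FAAH, the fatty acid amide hydrolase, ZNF276, LAMB2, MTA1, a NuRD complex subunit, and HDAC10. Another LAMB2 intron (smallest rise 35.5 points) ranked ahead of that of HDAC10 (35.4 points). LAMB2 intron 26 of 32 (chromosome 3, 49123374 to 49123446) went from 13.0% to 50.4% and to 66.7% after WBP11 and SNW1 RNAi, and from 31.9% to 80% after auxin. MTA1 intron 5 of 20 (chromosome 14, 105450185 to 105450260) went from 15.9% to 52.4% and 51.6%, and from 35.0% to 89.4%. FAAH rested on depths of 12.7 to 19.4.

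Higher introns were short in each comparison. Their median length was 175 bp after WBP11 RNAi (95% bootstrap interval 164 to 191), 224 bp after SNW1 RNAi (218 to 233) and 109 bp after WBP11 auxin (102 to 116), against 462, 595 and 626 bp for introns that neither rose nor fell. Random lists matched on mean retention had shorter introns than these, with medians of 347, 419 and 315 bp, but none of the 10000 had so low a median as the higher introns in any of the 3. Introns that fell after auxin had a median of 283.5 bp (241 to 334). Of introns of up to 80 bp, 24.3% rose after WBP11 RNAi (Wilson interval 21.6 to 27.4), 43.0% after SNW1 RNAi (39.9 to 46.2) and 64.7% after WBP11 auxin (61.7 to 67.5). Over 5000 bp the shares were 0.717%, 2.35% and 2.43%.

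**Figure D3:**
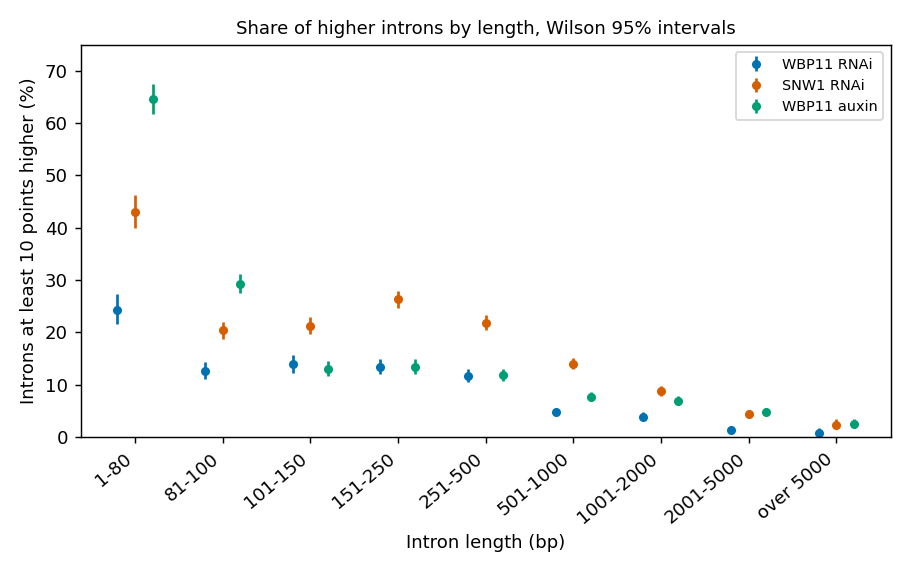
Share of tested introns at least 10 points higher (y axis, percent) by intron length (x axis, bp), with Wilson 95% intervals, for the 3 comparisons (colour). At up to 80 bp the shares are 24.3%, 43.0% and 64.7% after WBP11 RNAi, SNW1 RNAi and WBP11 auxin.

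**Figure D4:**
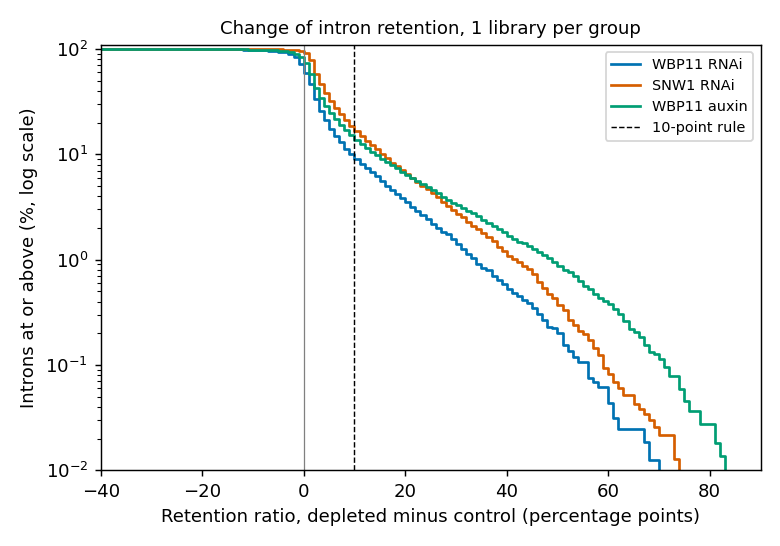
Share of tested introns (y axis, percent, log scale) whose retention ratio in the depleted library exceeds that in the control by at least the value on the x axis (percentage points). The dashed line marks the 10-point rule, which 9.07%, 16.6% and 13.8% of introns pass after WBP11 RNAi, SNW1 RNAi and WBP11 auxin.

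The counts of higher introns depended on the size rule and the depth. At a depth minimum of 50 they were 800 after WBP11 RNAi, 2299 after SNW1 RNAi and 1980 after WBP11 auxin. The tables list an intron only if it reached 1% retention in at least 1 of their libraries. Among introns that the control alone would list, a choice that favours high control values, 50.2%, 85.1% and 63.2% were above control, so the shift of the median after WBP11 RNAi was not seen in this subset, where 980 introns rose and 166 fell.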

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

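The tests of short introns against noise and of unspliced precursor RNA were chosen after the result was seen; the others in this part were set out before theirs.

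With 1 library per group, a difference between comparisons could only be noted, and none of the following was tested. Between WBP11 RNAi and WBP11 auxin, 43 introns moved by at least 10 points in opposite directions, against 50.9 for independent lists. Between WBP11 RNAi and SNW1 RNAi there were 39, against 50.2. Their shared control moves both changes the same way, so the 50.2 is too high a reference for this pair. Between SNW1 RNAi and WBP11 auxin there were 98, against 48.3, of which 90 rose after SNW1 RNAi and fell after auxin. The introns with the largest opposite changes in that pair, chosen after their values were seen, were in ZNF764 (45.1 and -34.9 points) and HDAC6 (43.0 and -30.4 points). The same ZNF764 intron, also chosen after its values were seen, had the largest opposite change between the WBP11 comparisons too, 50.6 points after RNAi against -34.9 after auxin. The list of anaphase-promoting complex and spindle checkpoint genes stood at opposite ends of its random lists, at percentile 2.23 after WBP11 RNAi and 98.96 after WBP11 auxin, a difference that was not tested; with unmatched random lists these were 3.50 and 94.6, both inside the outer 2.5% bounds, and the RNAi value was inside in 5 of 7 other settings.

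Retention was above control, by any amount, at most introns after SNW1 RNAi. Selection of introns by the depleted library does not account for it, since 85.1% of the 9222 introns that the control alone would list were above control by any amount. A uniform background such as genomic DNA is argued against by the added intron depth, which was 8.75 times larger in the top than in the bottom of 5 equal classes by control spliced reads (bootstrap interval 7.91 to 9.77). More unspliced precursor RNA of every intron alike stays open: within 412 genes, introns up to 150 bp gained a median of 1.02 points more than introns over 1000 bp (0.236 to 1.66), an interval on both sides of the 0.5 points up to which the test would have counted the gains as alike. Loss of SNW1 function, the biological explanation in the design, was not tested against it.

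More introns rose after WBP11 auxin than after WBP11 RNAi. For depth, the ratios of 10391 introns were redrawn at the lowest of each intron's depths in the 4 libraries. Auxin still had 1.88 times as many (1.83 to 1.93 over 20 draws, 1.98 before redrawing). The draws start from the observed ratios and keep their counting error. Depth is therefore argued against but not excluded. A low baseline of the auxin control is argued against by the ratio of 2.38 (2.26 to 2.5) when the auxin library was set against the RNAi control. The cell lines and the time and degree of depletion differ with the method and remain open as untested explanations.

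Introns that rose were short. Noise of short introns is argued against by the introns that fell, whose median length was at least 2.30 times that of those that rose in every comparison (1.52 to 3.15 in the comparison with the lowest ratio). Properties of the host gene do not account for the whole of it, since within genes that had both kinds the higher introns were the shorter in at least 60.6% of genes in every comparison (58.2 to 62.9, 1598 genes after SNW1 RNAi). GC content, which goes with short introns, was not analysed here and may be a candidate explanation, so a role of length itself remains a hypothesis.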

How the results depend on the processing

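Settings beyond those fixed before the data were examined are named as added. Numbers are in the order WBP11 RNAi, SNW1 RNAi, WBP11 auxin, higher then lower. The 4-fold rule, no depth minimum, median centring and introns without a known exon (added) kept all counts of higher introns within 1.5 times; of the lower counts under these settings, those that moved further were 143 for SNW1 RNAi with median centring. A 1.5-fold rule gave 6676 and 3870, 17942 and 774, 11427 and 2835, and a 2-fold rule (added) 4421 and 2069, 13403 and 361, 7859 and 1375; the share of higher among WBP11 RNAi calls went from 84.3% to 63.3% and 68.1%, and among auxin calls from 91.0% to 80.1% with 1.5-fold. A 2-fold rule with a pseudocount of 0.1 gave 714 and 95, 2259 and 13, 1714 and 73. A depth minimum of 50 gave 800 and 102, 2299 and 26, 1980 and 117, with fewer introns tested. Taking 1 intron per gene, that with the highest mean retention of both libraries, gave 745 and 172, 1714 and 52, 1520 and 169. Fewer introns were tested, and the choice uses the depleted library and so is not independent of the change. Added rules gave 2798 and 869, 7516 and 243, 5384 and 866 at 5 points, and 567 and 56, 1516 and 12, 1392 and 60 at 20 points. With the adjusted deposited p under 0.05 (added), WBP11 RNAi kept 792 and 70, and the lower introns of the others were 14 and 86; under 0.01 (added) the counts were 538 and 38, 2063 and 8, 1649 and 50. Introns without a warning in both libraries (added) gave 608 and 98, 1600 and 27, 1402 and 113, of fewer tested. In every setting more introns rose than fell.

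Introns higher in both were, for WBP11 RNAi with auxin, WBP11 RNAi with SNW1 RNAi and SNW1 RNAi with auxin, 392, 565 and 533 under the 4-fold rule and 442, 534 and 714 at a depth minimum of 50. The median length of higher introns was 159, 217 and 97 bp under the 4-fold rule, and 203 and 93 bp for SNW1 RNAi and auxin at a depth minimum of 50. A pseudocount of 10 reads gave 12.7% of WBP11 and 16.1% of SNW1 spliced reads remaining after their own RNAi, by its construction at low counts. Of 252 list percentiles under other settings, 211 kept their side of the outer 2.5% bounds, 21 lost it and 20 newly passed it. The p53 list after auxin and the U1 and U2 lists after both RNAi treatments kept it in all settings. The SR and CLK list did so in all settings for WBP11 RNAi. With 1 intron per gene (added for the lists) the SR and CLK list came to 3.62 after SNW1 RNAi and 10.7 after auxin. After SNW1 RNAi it came to 18.6 with lists matched on depth (added), and it also lost its side with unmatched random lists. Where no construction is named, the cause was not tested. Intron values relative to the gene's own value were not run, since the retention ratio is already relative to the splicing at the intron. Depth limits single introns: at the minimum of 10 a change of 10 points is within counting error.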

Other observations

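The tests of gene clustering and of the length profile, and the simulation of introns lower in all 3 comparisons, were chosen after the result was seen.

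Some genes kept many introns at once. COL7A1, a collagen gene with many short introns, had 16 of 29 tested introns higher after WBP11 RNAi, 41 of 58 after SNW1 RNAi and 27 of 42 after WBP11 auxin. NBEAL2 had 18 of 30, 20 of 37 and 16 of 35, and MAMDC4 15 of 20, 15 of 22 and 12 of 20. THOC6, a subunit of the THO mRNA export complex, had 10 of 10 higher after auxin, with a median rise of 29.4 points. These genes were chosen after their values were seen: the first 3 had the most higher introns in each RNAi comparison, and THOC6 was picked for its share, as 9 other genes had at least as many higher introns after auxin.

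Lower in all 3 comparisons were 11 introns, a number within the range of unchanged libraries with the RNAi control shared, which gave 5.66 on average and at most 13. For 7 of the 11 the interval of the difference reached 0 in at least 1 comparison. Of the other 4, chosen after their values were seen, AKAP8L intron 9 of 13 (chromosome 19, 15397856 to 15399301) went from 27.4% to 5.84% after WBP11 RNAi, to 17.3% after SNW1 RNAi and from 19.6% to 6.50% after auxin. RBM28 intron 7 of 18 (chromosome 7, 128335680 to 128335846) went from 28.3% to 5.35% and 16.3%, and from 15.2% to 2.76%. Both encode RNA-binding or nuclear matrix proteins, and the intervals of these differences excluded 0. EARS2 and MTF2 were the others. The RNAi comparisons share their control, so 2 of the 3 are not independent.

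A first hypothesis was that calls gather in genes beyond what intron length gives. Genes with at least 2 higher introns numbered 276 after WBP11 RNAi, where shuffling calls within 10 length classes gave 230 on average and at most 265. After SNW1 RNAi there were 782, with 806 on average, and after auxin 610, with 582 on average and at most 628. Only 1 of the 3 comparisons passed the highest of 1000 shuffles, so the prediction for all 3 was not met. Rises that pile up in few genes can lower this count. It therefore cannot decide whether calls gather in genes.

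A second hypothesis was that the length profile differs between the ways of removing WBP11. On the 8601 introns tested in all 3 comparisons, the share higher at up to 80 bp was 4.39 times that over 250 and up to 500 bp after auxin (bootstrap interval 3.92 to 5.00). It was 1.89 times after WBP11 RNAi (1.59 to 2.29) and 1.47 times after SNW1 RNAi (1.31 to 1.65). The intervals of the auxin and RNAi values do not overlap, which is consistent with a stronger dependence on length after auxin. With 1 library each, a difference between cell lines or treatments cannot be separated from a difference between these libraries.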
